A study of Homo sapiens with 12 samples.

How the data were processed

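RNA from Jurkat cells was made into stranded mRNA libraries and sequenced. The 12 libraries were grouped by their labels into 6 groups of 2, giving 3 comparisons: TAL1-KD against TAL1-control, UTX-KD against UTX-control, and J4-2uM against J4-control. Per the submitters' processing notes, TopHat2 2.0.12, HTSeq 0.6.1p1 and DESeq2 (version not stated) were used with the hg19 genome build. The annotation, the strand setting of the counting and the handling of reads with several positions were not stated. The authors deposited 1 table per comparison, holding raw read counts per Ensembl gene for each of its 4 libraries, with no normalization. Genes without a read in any library of a comparison were absent from its table. The log2 fold changes and standard errors deposited by the authors came from DESeq2, and small values for genes with few reads show that they were shrunk towards 0. The p-values deposited by the authors were raw and adjusted values from DESeq2, with no adjusted value for genes with few reads.

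All values reported here were recomputed from the deposited counts with R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, and libraries were scaled by TMM. Each comparison was fitted alone on its 4 libraries with the quasi-likelihood test of edgeR (two-sided), and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Of 29601, 29354 and 30716 genes in the tables for TAL1-KD, UTX-KD and GSK-J4, 16829, 16847 and 17907 were tested. The standard error of a log2 fold change was its size over the root of the F statistic. In the deposited tables, adjusted p-values under 0.05 numbered 4131 higher and 3848 lower for TAL1-KD, 2839 and 3539 for UTX-KD, and 5658 and 5766 for GSK-J4. Of these, 7838, 6359 and 11352 were also called here, and none in the opposite direction.

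Gene symbols came from GENCODE 29, which also gave transcript length and GC content, and 27917, 27684 and 28927 of the identifiers matched a symbol. Older symbols were resolved with the RefSeq gene table of GRCh38.p14. No hg19 annotation was used here, so no coordinates are given. The design, the tests, the alternatives and the 34 gene lists were fixed before the data were examined. Of 649 list entries, 619 matched by symbol and 28 by an older symbol, and 2 had no identifier. Lists were tested with cameraPR of limma 3.58.1 on signed z values with a preset correlation of 0.01, and with camera and an estimated correlation. The planned fry test of limma, which does not set a list against other genes, was also run within each comparison. The p-values of each test were adjusted by Benjamini-Hochberg over the lists of a comparison. Genes encoded in the mitochondrial genome have no entry in the tables and are not analysed here.

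Overlaps between comparisons were set against the product of the numbers of calls over the genes tested in both, with Fisher's exact test. Differences between comparisons were tested in edgeR as the interaction of treatment and comparison over 8 libraries. Correlations are across genes and carry no p-value, since genes are not independent replicates. Named genes were the targets and, per comparison and direction, the 8 largest log2 fold changes among called genes with a symbol and a mean normalised count of at least 50. For each list up to 4 called members with the smallest adjusted p were eligible, and some of these are not reported here. For overlaps, up to 8 genes per direction were ranked by the smaller absolute change, and for differences 5 per direction with the largest z and opposite calls. Reads on nuclear pseudogenes of mitochondrial genes were summed after their values were seen.

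Depth ran from 55524079 to 82534711 counted reads per library. The biological coefficient of variation was 8.40% in the TAL1-labelled comparison, 2.30% in the UTX-labelled one and 2.69% with GSK-J4. The procedure was tested on simulated data with the depth and spread of each comparison, in which 67, 67 and 66 genes changed by 1.25-fold, 1.5-fold and 2-fold. So few changed genes make the adjusted threshold stricter than in the data, so the shares recovered are not those of the data. These sizes of change were recovered in 2.99%, 61.2% and 92.4% of genes for the TAL1 setting, where 18 of 122 calls were false. For the UTX setting they were recovered in 71.6%, 91.0% and 100% of genes, with 15 false of 190 calls, and for the GSK-J4 setting in 77.6%, 91.0% and 100%, with 6 false of 185. The share of false calls was above the nominal 0.05 in the TAL1 and UTX settings.

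The alternatives tried were other thresholds, a fold change minimum, no filter and a stricter filter on low counts, size factors of DESeq2 and its Wald test (DESeq2 1.42.0), a replicate block, each library left out, a larger preset correlation, log2 fold changes as the list statistic, and another background. After the data were examined, removal of each library's trend with GC content and transcript length was added, as were the counts and correlations that the closing section names.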

Results

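Messenger RNA was sequenced from Jurkat cells, a human T-cell acute lymphoblastic leukaemia line that expresses the blood stem cell transcription factor TAL1. The 12 libraries formed 6 groups of 2. Cells carrying a doxycycline-inducible shRNA against TAL1 were grown without doxycycline (TAL1-control) or with it (TAL1-KD). Cells carrying an inducible shRNA against UTX were grown in the same way (UTX-control and UTX-KD). UTX is the product of KDM6A, a demethylase that removes a repressive Polycomb mark from histones. Other Jurkat cells received vehicle (J4-control) or GSK-J4 (J4-2uM), a small-molecule inhibitor of KDM6 demethylases. Doxycycline was given at 5 µg/ml and GSK-J4 at 2 µM, each for 72 h. The counted reads per library ranged from 55524079 to 82534711. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

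The first question was whether each targeted mRNA was lower in the libraries labelled as its knockdown. TAL1 (ENSG00000162367) had a normalised read count of 276 ± 2.51 CPM (TMM-scaled, SD, n = 2) in TAL1-control and 261 ± 21.5 in TAL1-KD. Its log2 fold change was -0.07 with a 95% interval of -0.27 to 0.13, and the edgeR quasi-likelihood test gave an adjusted p of 0.490. KDM6A (ENSG00000147050) stood at 31.2 ± 0.0583 CPM (SD, n = 2) in UTX-control and 30.1 ± 0.0696 in UTX-KD. Its log2 fold change was -0.08 with a 95% interval of -0.17 to 0.00, and the edgeR adjusted p was 0.103. Neither targeted mRNA was therefore shown to be lower in its own libraries, and these comparisons are named here by their labels only. KDM6B (ENSG00000132510), a second demethylase of the same histone mark, rose in all 3 comparisons. Its log2 fold change was 0.93 (SE 0.08) in the TAL1-labelled comparison, 0.45 (SE 0.03) in the UTX-labelled one and 0.39 (SE 0.03) with GSK-J4. With GSK-J4, KDM6A rose by 0.44 (SE 0.04) on the log2 scale and the related gene UTY by 0.71 (SE 0.04). UTY also rose in the TAL1-labelled comparison, by 0.45 (SE 0.08), and in the UTX-labelled one, by 0.30 (SE 0.04). TAL1 mRNA fell with GSK-J4, from 187 ± 0.142 to 116 ± 2.79 CPM (SD, n = 2), a log2 fold change of -0.66 (SE 0.03, edgeR adjusted p = 6.02e-10). In the UTX-labelled comparison TAL1 changed by -0.12 (SE 0.03, edgeR adjusted p = 0.00155).

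**Figure D1:**
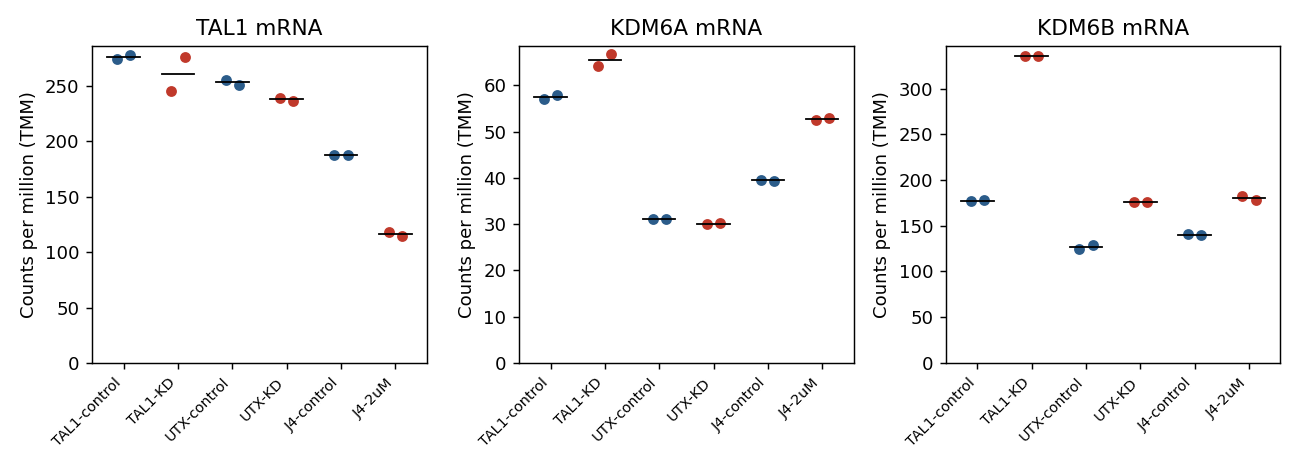
TMM-scaled CPM (y axis) of TAL1, KDM6A and KDM6B in each of the 6 groups (x axis), with 1 point per library and a bar at the mean of 2. TAL1 fell from 187 to 116 with GSK-J4, whereas the means in TAL1-control and TAL1-KD were 276 and 261.

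In the libraries labelled TAL1 knockdown, NF-kB pathway genes and the ferritin genes FTL and FTH1 were higher, and mitotic, DNA replication and thymocyte genes were lower. By camera these 4 lists were shifted, but with adjusted p = 0.412 to 0.514 with an estimated correlation. RELB, a transcription factor subunit of the NF-kB family, rose by 3.41 (SE 0.10, n = 2 per group) on the log2 scale. CHRNA6, a nicotinic receptor subunit, rose by 3.51 (SE 0.24), and FTL, the light chain of the iron store ferritin, by 2.55 (SE 0.13). TKTL1, a transketolase-like enzyme, changed by -3.45 (SE 0.15), HOXA13, a homeobox gene, by -3.01 (SE 0.27) and RAG2, part of the V(D)J recombinase, by -2.39 (SE 0.29). Because TAL1 mRNA was not shown to be lower in these libraries, the directions are those of the labelled groups.

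Other large increases in the TAL1-labelled comparison were those of the heat shock gene HSPA6 (2.79), ARRDC3 (2.77), the phosphatase gene DUSP8 (2.74), the ferritin pseudogene FTLP3 (2.51) and the small GTPase gene RND1 (2.43). Other large decreases were those of ARHGEF39 (-3.14), SDCBP2-AS1 (-3.07), CENATAC-DT (-2.95), STARD4-AS1 (-2.88), FAR2 (-2.87) and the dynein gene DNAH6 (-2.84). FTL and FTLP3, and HSPA6 with its relatives, have closely similar sequences, and the antisense and divergent transcripts overlap or adjoin other genes, so the source of their reads is uncertain.

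Among 22 activation-induced and NF-kB target genes, 15 rose and 2 fell in the TAL1-labelled comparison, with a median log2 fold change of 1.13. JUN rose by 2.12 (SE 0.10), the inhibitor NFKBIA by 2.09 (SE 0.10) and the adhesion molecule ICAM1 by 1.92 (SE 0.09). The camera test gave an adjusted p of 4.21e-06 for this list, and adjusted p = 0.412 with an estimated correlation. Of 8 genes of iron handling 3 rose, namely FTL, the other ferritin chain FTH1 (1.67) and the transferrin receptor TFRC (1.32). Ferritin stores iron and TFRC imports it. Camera gave this list an adjusted p of 0.0427, and adjusted p = 0.412 with an estimated correlation. Of 12 NRF2 targets, which act against oxidative stress, 8 rose, with OSGIN1 at 2.26 and GCLC at 0.69 (camera adjusted p = 0.000399, adjusted p = 0.412 with an estimated correlation). Of 5 genes of the metallothionein list, whose products bind or handle metals, 4 rose, with MT1X at 1.07 and the zinc exporter SLC30A1 at 0.98 (camera adjusted p = 0.0169, adjusted p = 0.437 with an estimated correlation).

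Of 24 genes of the G2 phase and mitosis, 22 fell in the TAL1-labelled comparison, with a median of -0.74. The motor gene CENPE fell by 2.65 (SE 0.16) on the log2 scale, HMMR by 2.43 (SE 0.17), the kinase gene AURKA by 1.38 (SE 0.08) and the cyclin gene CCNB1 by 1.22 (SE 0.08). The camera test gave an adjusted p of 1.15e-09, and adjusted p = 0.437 with an estimated correlation. Of 31 DNA replication genes 29 fell, with a median of -0.63, among them POLA1 (-1.72) and PRIM1 (-1.38), which encode parts of the primase complex (camera adjusted p = 2.28e-10, adjusted p = 0.412 with an estimated correlation).

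Cholesterol, ribosomal protein, respiratory chain and endoplasmic reticulum stress genes were shifted upwards in the TAL1-labelled comparison by camera, but with adjusted p = 0.515 to 0.696 with an estimated correlation. Of 19 genes of cholesterol metabolism, 17 rose and 1 fell, with a median of 0.88. The synthesis enzyme genes DHCR7 and SQLE rose by 1.79 (SE 0.21) and 1.31 (SE 0.17). Camera gave an adjusted p of 8.77e-06, and adjusted p = 0.613 with an estimated correlation. Of 74 ribosomal protein genes 56 rose, with a median of 0.54, for example RPL38 (0.92) and RPL24 (0.89), and camera gave adjusted p = 2.28e-10, against adjusted p = 0.696 with an estimated correlation. Many ribosomal protein genes have processed pseudogenes that can share their reads. Of 33 nuclear genes of the respiratory chain, 23 rose and 1 fell, with NDUFA2 at 1.29 and COX7A2 at 1.17 (camera adjusted p = 3.59e-06, adjusted p = 0.696 with an estimated correlation). Of 17 endoplasmic reticulum stress genes, 13 rose and 1 fell, with the chaperone gene HSPA5 at 0.98 and HERPUD1 at 0.91 (camera adjusted p = 0.000157, adjusted p = 0.515 with an estimated correlation).

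Of 19 thymocyte stage genes, 13 fell and 1 rose in the TAL1-labelled comparison, with a median of -0.68. The coreceptor gene CD4 fell by 1.32 (SE 0.14) and DNTT, which adds bases at V(D)J joints, by 0.88 (SE 0.09). By camera the adjusted p was 0.00296, and adjusted p = 0.514 with an estimated correlation. Of 7 GIMAP genes, which encode lymphocyte GTPases, 5 fell, with GIMAP1 at -1.04 and GIMAP7 at -0.82 (camera adjusted p = 0.0339, adjusted p = 0.514 with an estimated correlation). Of 15 p53 targets, 10 rose and 1 fell, with the cell cycle inhibitor CDKN1A at 1.99 and the BCL2 family killer BBC3 at 1.23 (camera adjusted p = 0.0110, adjusted p = 0.422 with an estimated correlation). Of 25 apoptosis genes, 14 rose and 4 fell, with BIRC3, an inhibitor of cell death, at 1.51 (camera adjusted p = 0.0101, adjusted p = 0.422 with an estimated correlation).

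Genes tied to TAL1 itself moved both ways. Of 9 members of its regulatory circuit 3 rose and 3 fell. GATA3 (1.46), TCF3 (0.70) and LDB1 (0.44) rose, and LYL1, a close relative of TAL1, changed by -1.40. Of 11 genes described in the literature as activated by TAL1, 5 fell and 2 rose, with ERG at -1.50, ETV6 at -0.81 and ALDH1A2 at -0.57. Camera found no shift of either list, with adjusted p = 0.803 for the circuit and 0.198 for the activated genes. Part of that literature used Jurkat cells, so the list is not fully independent of the cell line.

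In the TAL1-labelled comparison 4424 genes were higher and 4696 lower of 16829 tested, by edgeR at an adjusted p under 0.05, and 700 and 1761 of these changed at least by 1 on the log2 scale. Adjusted over the list alone, some counts changed and the others were the same. Higher were then 60 ribosomal, 15 endoplasmic reticulum stress, 9 NRF2, 6 T-cell receptor, 2 thymocyte and 2 glycolytic genes. Also higher were 2 cyclin-dependent kinase inhibitor genes and 7 genes of KDM6 demethylases and their partners. Lower were 6 GIMAP, 14 thymocyte, 5 apoptosis and 2 cyclin-dependent kinase inhibitor genes, 8 genes described as activated by E proteins, and 0 myeloid markers. The E protein list moved both ways, with 5 of its 13 genes higher, and camera found no shift (adjusted p = 0.492). The spread between the TAL1-KD libraries was wider than in any other group, with an SD of log2 differences of 0.256 against 0.108 in TAL1-control. Without TAL1-control replicate 1, 2431 genes were higher and 3094 lower, and without TAL1-control replicate 2, 2657 were higher.

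In the libraries labelled UTX knockdown, genes of amino acid stress were higher, and genes of mitosis, glycolysis, hypoxia and cholesterol synthesis were lower. These list shifts were called by camera, but with adjusted p = 0.178 to 0.345 with an estimated correlation. ASS1, an enzyme of arginine synthesis, rose by 2.59 (SE 0.04, n = 2 per group) on the log2 scale, and ASNS, the asparagine synthetase, by 2.05 (SE 0.05). The thymic homing receptor CCR9 rose by 2.49 (SE 0.08) and the glycine transporter SLC6A9 by 2.38 (SE 0.08). AK4, a mitochondrial adenylate kinase, changed by -3.50 (SE 0.14), and MIR210HG, the host transcript of a hypoxia-induced microRNA, by -3.38 (SE 0.11). KDM6A mRNA was not shown to be lower in these libraries, so the directions are those of the labelled groups.

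Further large increases in the UTX-labelled comparison were those of the fucosyltransferase gene FUT1 (3.19), L3MBTL2-AS1 (2.71), DUSP8 (2.31), the matrix gene MFAP4 (2.23) and CHAC1 (2.11), which degrades glutathione. Further large decreases were those of the receptor gene GPR146 (-3.27) and of 5 nuclear pseudogenes of mitochondrial genes, MTCYBP18 (-3.36), MTCO2P12 (-3.18), MTCO3P12 (-3.13), MTCO2P22 (-2.96) and MTND6P4 (-2.94). These pseudogenes can share reads with mitochondrial transcripts, which the tables do not list.

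Of 24 genes of the ATF4 and integrated stress response, 23 rose and 1 fell in the UTX-labelled comparison, with a median of 0.97. CHAC1 rose by 2.11 (SE 0.06), ASNS by 2.05 (SE 0.05), the stress sensor SESN2 by 1.45 (SE 0.04) and the transcription factor ATF5 by 1.24 (SE 0.04). The camera test gave an adjusted p of 3.75e-18, and adjusted p = 0.178 with an estimated correlation. Of 15 glycolytic enzymes 14 fell, with a median of -0.76, among them lactate dehydrogenase LDHA (-1.42), hexokinase HK2 (-1.28), TPI1 (-1.07) and ENO1 (-1.04). The list's camera adjusted p was 8.43e-13, and adjusted p = 0.345 with an estimated correlation. Of 19 HIF targets of the hypoxia response, 16 fell and 2 rose, with a median of -0.85, among them PFKFB4 (-2.18), BNIP3 (-1.84) and BHLHE40 (-1.72). In the camera test the adjusted p was 1.48e-10, and adjusted p = 0.345 with an estimated correlation. LDHA is on both of these lists.

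All 19 cholesterol genes measured in the UTX-labelled comparison fell, with a median of -0.62, and HMGCS1 (-1.10), LSS (-0.87) and FDPS (-0.83) were among them. Camera gave an adjusted p of 5.93e-17, and adjusted p = 0.178 with an estimated correlation. All 24 mitotic genes fell, with a median of -0.64, among them CCNB1 (-1.14), PLK1 (-0.92), HMMR (-0.86) and CDC20 (-0.86), and 28 of 31 DNA replication genes fell, with GINS1 at -0.69 and FEN1 at -0.56. Camera gave adjusted p = 4.49e-21 for mitosis and 8.62e-15 for replication, against adjusted p = 0.249 and 0.345 with an estimated correlation.

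Of 22 activation and NF-kB genes 13 rose in the UTX-labelled comparison, with RELB at 1.90, JUN at 1.17 and TNFAIP3 at 0.88 (camera adjusted p = 0.000297, adjusted p = 0.345 with an estimated correlation). Of 15 p53 targets 8 rose and 1 fell, with BBC3 at 1.46 and TP53INP1 at 1.26 (camera adjusted p = 0.00168, adjusted p = 0.345 with an estimated correlation). Of 74 ribosomal protein genes 49 rose and 1 fell, by a median of 0.12, with RPL26 and RPS18 at 0.31 (camera adjusted p = 2.06e-07, adjusted p = 0.802 with an estimated correlation). Of 33 nuclear respiratory chain genes 19 fell and 1 rose, with SDHA at -0.32 (camera adjusted p = 0.00499, adjusted p = 0.802 with an estimated correlation). Of 21 T-cell receptor signalling genes 12 rose and 3 fell, with CD2 at 0.37 and CD3E at 0.33 (camera adjusted p = 0.00538, adjusted p = 0.410 with an estimated correlation). Of 25 interferon-stimulated genes 13 rose and 4 fell, with IRF7 at 0.87 and STAT2 at 0.61 (camera adjusted p = 0.0389, adjusted p = 0.345 with an estimated correlation). Of 11 genes described as activated by TAL1, 8 fell and 2 rose, with CDK6 at -0.22, and camera gave adjusted p = 0.199. Of 19 thymocyte genes 8 fell and 2 rose, with RAG1 at -0.52 and CD38 at 0.76, and camera gave adjusted p = 0.0947. In the TAL1 circuit 5 of 9 rose and 2 fell, with GATA3 at 0.42 and LMO1 at -0.79, and camera gave adjusted p = 0.407.

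In the UTX-labelled comparison 4240 genes were higher and 4269 lower of 16847 tested, by edgeR at an adjusted p under 0.05. Of these, 298 and 172 changed at least by 1 on the log2 scale. Adjusted over the list alone, some counts changed and the others were the same. Higher were then 51 ribosomal, 13 T-cell receptor and 14 interferon genes. Lower were 3 ribosomal, 10 endoplasmic reticulum stress and 8 Polycomb repressive complex genes. The DESeq2 Wald test called 2801 genes higher in place of 4240.

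With GSK-J4, NF-kB, metal-binding and p53 target genes were higher, and glycolytic, hypoxia and thymocyte genes and MYC were lower. Camera called these list shifts, but with adjusted p = 0.388 to 0.408 with an estimated correlation. CXCL10, a T-cell attracting chemokine, rose by 4.89 (SE 0.36, n = 2 per group) on the log2 scale, DUSP8 by 4.34 (SE 0.07), BCL3, a regulator of NF-kB, by 3.73 (SE 0.10) and RELB by 3.46 (SE 0.06). MT1X, a metallothionein, rose by 3.05 (SE 0.14). The oncogene MYC changed by -3.44 (SE 0.04), RAG2 by -3.97 (SE 0.08) and HK2 by -2.55 (SE 0.04).

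Other large increases with GSK-J4 were those of the cadherin gene CDH3 (3.72), CPNE4 (3.62), HSPA6 (3.51) and LINC01749 (3.47). The 8 largest decreases were all mitochondrial pseudogenes, from MTND6P4 (-8.55, SE 0.25) and MTATP8P1 (-8.21, SE 0.07) through MTND4LP1 (-7.71), MTND4LP30 (-7.66), MTCYBP18 (-7.23), MTCO1P12 (-7.17) and MTND4P24 (-7.00) to MTCO3P12 (-6.97).

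Of 15 glycolytic enzymes 14 fell and 1 rose with GSK-J4, with a median of -1.36. HK2 fell by 2.55 (SE 0.04), LDHA by 2.33 (SE 0.04), PGK1 by 1.94 (SE 0.04) and ENO1 by 1.92 (SE 0.04) on the log2 scale. By camera the adjusted p was 1.90e-07, and adjusted p = 0.388 with an estimated correlation. Of 20 HIF targets 17 fell and 3 rose, with a median of -1.21, among them BNIP3 (-2.26), PFKFB4 (-2.20) and the glucose transporter SLC2A1 (-1.89). The list's camera adjusted p was 2.13e-05, and adjusted p = 0.408 with an estimated correlation. Of 20 cholesterol genes 15 fell and 3 rose, with LSS at -1.61 and HMGCS1 at -1.32 (camera adjusted p = 0.000737, adjusted p = 0.388 with an estimated correlation). Of 33 nuclear respiratory chain genes 24 fell and 7 rose, with COX5A at -0.74 (camera adjusted p = 0.00184, adjusted p = 0.747 with an estimated correlation). Of 74 ribosomal protein genes 55 fell and 4 rose, by a median of -0.22, with RPL7A and RPS16 at -0.55 (camera adjusted p = 9.34e-06, adjusted p = 0.749 with an estimated correlation). Of 13 NRF2 targets 9 fell and 2 rose, with a median of -0.47 and a mean of -0.06, and TALDO1 (-0.90) and TKT (-0.85), both of the pentose phosphate pathway, fell (camera adjusted p = 0.0211, adjusted p = 0.515 with an estimated correlation).

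Several other lists were shifted upwards with GSK-J4 by camera, but with adjusted p = 0.388 to 0.512 with an estimated correlation. Of 22 activation and NF-kB genes 18 rose and 2 fell, with JUN at 2.18, TNFAIP3 at 2.12 and NFKB2 at 1.86 (camera adjusted p = 0.000259, adjusted p = 0.388 with an estimated correlation). Of 15 p53 targets 12 rose and 2 fell, with BBC3 at 2.68, CDKN1A at 1.96 and FDXR at 1.37 (camera adjusted p = 0.000259, adjusted p = 0.408 with an estimated correlation). Of 26 apoptosis genes 17 rose and 6 fell, with BBC3, BIRC3 (1.38), BAK1 (1.31) and BMF (1.27) among those that rose (camera adjusted p = 0.0114, adjusted p = 0.388 with an estimated correlation). Of 25 ATF4 response genes 15 rose and 5 fell, with PPP1R15A at 2.86, ATF5 at 2.33, ATF3 at 2.27 and DDIT4 at -1.73 (camera adjusted p = 0.00323, adjusted p = 0.512 with an estimated correlation). Of 6 genes of the metallothionein list 5 rose, among them MT1F (3.04), MT2A (2.97) and SLC30A1 (2.60). In the camera test the adjusted p was 0.00881, and adjusted p = 0.408 with an estimated correlation, and metallothionein genes have closely similar copies that can share reads. Of 25 interferon-stimulated genes 17 rose and 5 fell, with IRF7 at 2.48 and IFIT3 at 1.59 (camera adjusted p = 0.00690, adjusted p = 0.408 with an estimated correlation). Endoplasmic reticulum stress genes were not shifted, with 9 higher and 7 lower of 17 and a camera adjusted p of 0.680.

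Of 19 thymocyte genes 15 fell and 3 rose with GSK-J4, with a median of -0.93, among them RAG2, RAG1 (-1.73), CD1A (-1.23) and the transcription factor TCF7 (-1.09). Camera gave an adjusted p of 0.000259, and adjusted p = 0.388 with an estimated correlation. All 7 GIMAP genes fell, with GIMAP4 at -1.15 (camera adjusted p = 0.00323, adjusted p = 0.512 with an estimated correlation). Of 21 T-cell receptor signalling genes 13 fell and 4 rose, with GRAP2 at -1.29 and CD247 at -0.83 (camera adjusted p = 0.0456, adjusted p = 0.593 with an estimated correlation). Of 24 mitotic genes 15 fell and 6 rose, with CCNB1 at -2.27, PLK1 at -1.44 and KIF20A at -1.31 (camera adjusted p = 0.00325, adjusted p = 0.408 with an estimated correlation). DNA replication genes went both ways, 13 higher and 11 lower of 31, with CDT1 at 1.06 and CDC6 at 0.64, and camera gave adjusted p = 0.735. Of 12 genes described as activated by TAL1, 8 fell and 3 rose, with ALDH1A2 at -2.02, TRIB2 at -1.23 and CDK6 at -1.09, and camera gave adjusted p = 0.0659. In the TAL1 circuit 6 of 9 fell and 2 rose, with RUNX1 at -1.20, MYB at -0.62 and GATA3 at 0.77, and camera gave adjusted p = 0.154.

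With GSK-J4, 6794 genes were higher and 6616 lower of 17907 tested, by edgeR at an adjusted p under 0.05, and 1770 and 1618 of these changed at least by 1 on the log2 scale. Adjusted over the list alone, the counts were the same except for 25 respiratory chain genes lower, 19 activation genes higher, 1 metallothionein list gene lower, 12 DNA replication genes lower and 4 TAL1-activated genes higher. No list shift named here in any of the 3 comparisons kept an adjusted p under 0.05 with an estimated correlation. The estimates varied widely between lists. In the TAL1-labelled comparison they were 0.992 for ribosomal, 0.706 for cholesterol and 0.629 for respiratory chain genes, but 0.0441 for DNA replication genes. Where the estimate lay far above the preset 0.01, camera at that preset may overstate a shift. The test with an estimated correlation rested on 2 residual degrees of freedom in each comparison, so a lost call does not decide against a shift. All 19 cholesterol genes fell in the UTX-labelled comparison, for example, at adjusted p = 0.178. By fry that list had adjusted p = 0.00327, and DNA replication in the TAL1-labelled comparison 0.0132. Cholesterol and ribosomal genes in the TAL1-labelled comparison were among those not called by fry, with adjusted p = 0.0971 and 0.156. Fry cannot restore a lost camera call, since it does not set a list against other genes. In the 3 comparisons 54.2%, 50.5% and 74.9% of tested genes were called. With GSK-J4 fry also called endoplasmic reticulum stress genes (adjusted p = 0.0373), of which 9 rose and 7 fell. It called the TAL1 circuit and the TAL1-activated list lower there as well (adjusted p = 0.00444 for both).

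**Figure D2:**
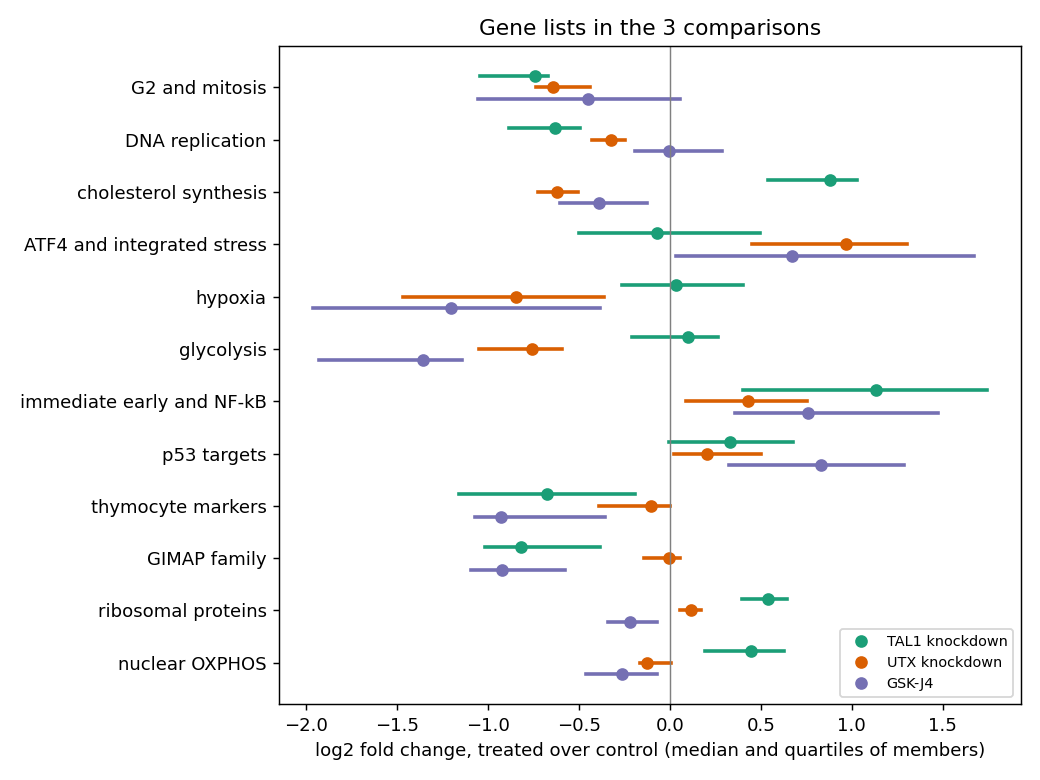
Median log2 fold change, treated over control (x axis), of the measured members of 12 gene lists (y axis) in the 3 labelled comparisons; lines span the quartiles. Cholesterol genes had a median of 0.88 in the TAL1-labelled comparison and -0.62 in the UTX-labelled one, and glycolytic genes had -1.36 with GSK-J4.

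Reads on nuclear pseudogenes of mitochondrial genes moved with every treatment, and this class was chosen after its values were seen. They took 2.31 ± 0.0757% of counted reads (SD, n = 2) in TAL1-control and 1.11 ± 0.0255% in TAL1-KD. The share was 1.87 ± 0.0404% in UTX-control and 0.298 ± 0.0385% in UTX-KD. It was 2.55 ± 0.0525% in J4-control and 0.0294 ± 0.00241% in J4-2uM. Of 24 such pseudogenes tested in each comparison, 17, 24 and 24 fell, with median log2 fold changes of -0.79, -2.73 and -6.66.

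**Figure D3:**
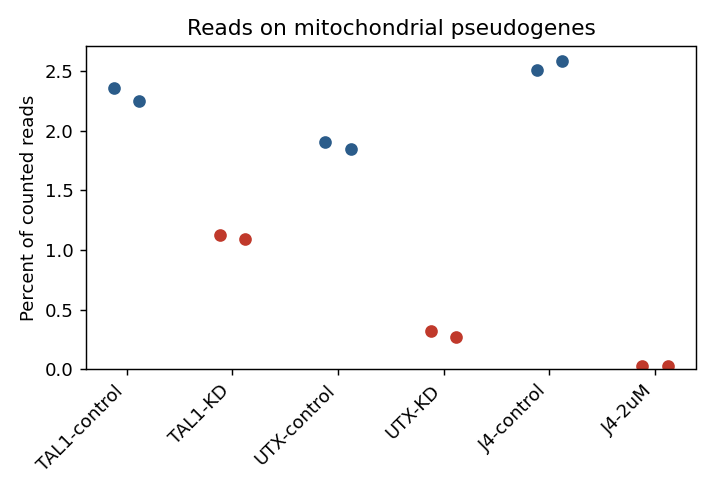
Percent of counted reads on mitochondrial pseudogenes (y axis) in each library of the 6 groups (x axis), with 1 point per library. In each pair of groups both treated libraries lie below both controls, down to a mean of 0.0294% with GSK-J4.

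The next question was how far the treatments changed the same genes. With no fold minimum, the UTX-labelled and GSK-J4 comparisons shared the most genes: 2979 genes were lower in both, against 1654.6 by chance, and 2853 were higher in both, against 1579.3 by chance, over 16619 genes tested in both. Fisher's exact test (two-sided, across genes, which are not independent replicates) gave odds ratios of 5.96 and 5.60. GPR146 (-3.27 and -4.35), MIR210HG (-3.38 and -4.04), GAB2 (2.07 and 3.33) and CCR9 (2.49 and 2.14) were among the genes that moved alike. With a log2 fold change of at least 1 this pair shared 103 lower and 176 higher genes, against 458 and 248 for the TAL1-labelled and GSK-J4 comparisons. Only 172 lower and 298 higher genes passed this minimum in the UTX-labelled comparison, against 1761 and 700 in the TAL1-labelled one. Relative to chance, given in the closing section, the UTX-labelled and GSK-J4 pair still shared the most. Across genes, Pearson's r of the log2 fold changes was 0.558 and Spearman's rho 0.505. The TAL1-labelled and UTX-labelled comparisons shared 1579 lower genes (1188.5 by chance, odds ratio 1.80, Fisher's exact p = 1.23e-52) and 1653 higher genes (1126.2 by chance, odds ratio 2.25, exact p = 3.44e-96) of 16179. VIL1 (-1.59 and -1.56) fell and CRIM1 (1.98 and 1.72) rose in both, and r across genes was 0.159, with rho 0.152. The TAL1-labelled and GSK-J4 comparisons shared 2380 lower genes (1759.5 by chance, odds ratio 2.17, exact p = 1.37e-106) and 2323 higher genes (1697.3 by chance, odds ratio 2.23, exact p = 2.81e-111) of 16573. TERT, the telomerase catalytic subunit, fell in both (-2.59 and -2.80), and KREMEN2 (2.43 and 2.82) rose, with r at 0.288 and rho at 0.254. In each of the 3 pairs the comparisons had separate control libraries. TAL1-KD and UTX-KD both received doxycycline, which their controls did not, and no library had doxycycline alone. For genes shared by these comparisons, effects of doxycycline and of the shRNAs cannot be told apart.

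In all 3 comparisons 1124 genes fell, against 461 by chance, and 1291 rose, against 431 by chance, of 16103 tested in each. DUSP8, RELB, BCL3, CCR9 and CHRNA6 rose in each by at least 1.72, the smallest of these values being that of CHRNA6 in the UTX-labelled comparison. MIR210HG, GPR146 and AK4 fell in each, AK4 by 1.98, 3.50 and 1.66 on the log2 scale.

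**Figure D4:**
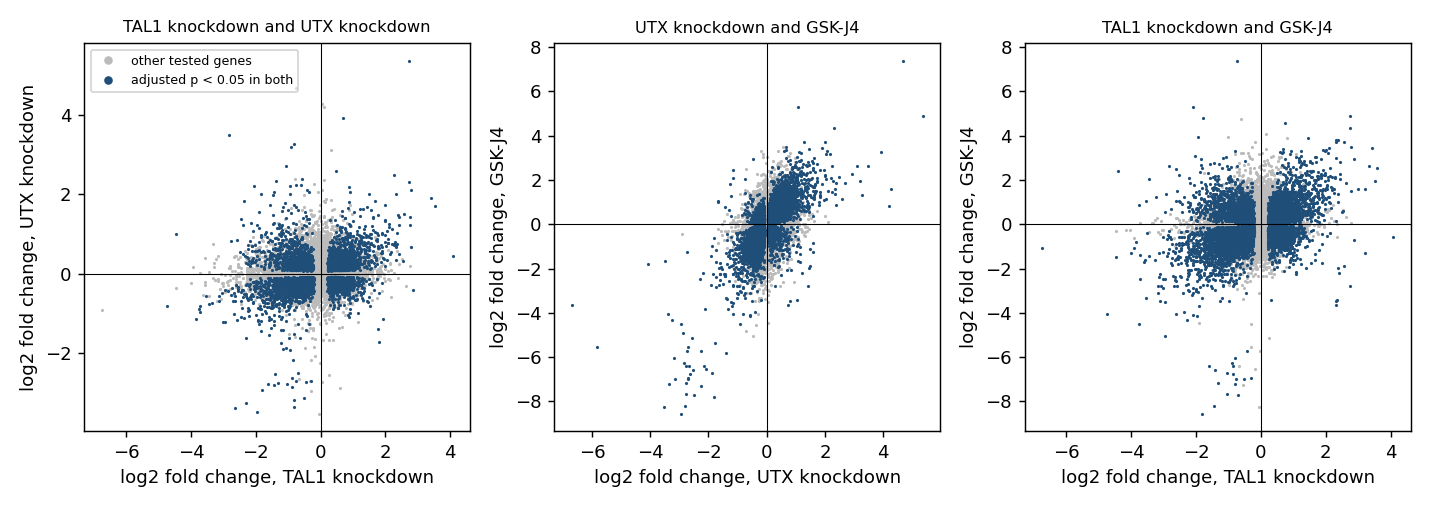
Log2 fold changes of each gene in pairs of comparisons (both axes), with genes past an edgeR adjusted p of 0.05 in both in dark blue and other tested genes in grey. Pearson's r across genes was 0.159, 0.558 and 0.288 from left to right.

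Many genes changed differently between treatments, by the edgeR test of the difference itself. Between the TAL1-labelled and UTX-labelled comparisons 8740 of 16179 genes differed, and 1812 genes were called in opposite directions. PRDX1, a peroxide-removing enzyme, rose by 1.66 (SE 0.10) in the TAL1-labelled comparison and changed by -0.42 (SE 0.03) in the UTX-labelled one, and TFRC changed by 1.32 and -0.16. ASNS changed by -0.35 and 2.05, and PCK2, a mitochondrial enzyme of glucose synthesis, by -1.01 and 1.04. Between the UTX-labelled and GSK-J4 comparisons 10481 of 16619 genes differed, with 1342 opposite calls. ARPP21 changed by 0.09 and -1.61, IGF2R by 0.20 and -1.15, PEA15 by -0.14 and 1.15, and the cell cycle phosphatase CDC25A by -0.33 and 0.77. Between the TAL1-labelled and GSK-J4 comparisons 9599 of 16573 genes differed, with 2626 opposite calls. MYC changed by 0.30 and -3.44, the chaperonin partner HSPE1 by 1.23 and -1.79, and TKTL1 by -3.45 and 2.04.

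Gene lists differed between the labelled shRNA comparisons as well. The ATF4 response list had a median of 0.97 in the UTX-labelled comparison and -0.07 in the TAL1-labelled one, where 8 of 25 genes rose and 11 fell, with a mean of 0.03. Over the 24 genes measured in both, the camera test of the difference gave an adjusted p of 3.50e-07, and adjusted p = 0.0185 with an estimated correlation. The cholesterol list differed with an adjusted p of 1.38e-08, but adjusted p = 0.317 with an estimated correlation. Glycolysis (3 higher and 2 lower of 15) and hypoxia (5 higher and 3 lower of 19) were not shifted in the TAL1-labelled comparison by camera, with adjusted p = 0.644 and 0.659. Their differences from the UTX-labelled comparison had adjusted p = 4.42e-05 and 2.96e-06, and adjusted p = 0.320 for both with an estimated correlation.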

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

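Of the tests in this part, those on GC content and transcript length and the one on shared sequence of mitochondrial pseudogenes had their bounds written before their results were seen, and all other tests of an explanation were chosen only after the result was seen.

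The labelled shRNA comparisons differed from each other. By the edgeR test of the difference, 8740 genes changed differently between the TAL1-labelled and the UTX-labelled comparison. The log2 difference, TAL1-labelled minus UTX-labelled, was 2.10 for PRDX1, 1.53 for HSPH1, 1.503 for TFRC, 1.52 for CCDC86 and 1.34 for TWNK. It was -2.81 for MFAP4, -1.88 for SESN2, -2.03 for PCK2, -2.37 for ASNS and -2.38 for SPNS3. Among gene lists, the median difference was -0.88 for the ATF4 response, 1.54 for cholesterol synthesis, 0.96 for glycolysis, 0.82 for hypoxia and 0.83 for metallothioneins. It was 0.78 for NRF2 targets, 0.55 for the nuclear respiratory chain, 0.76 for replication histones and 0.45 for endoplasmic reticulum stress. By camera on the difference, the replication histones had an adjusted p of 0.0430 and the other 8 lists lower values. With an estimated correlation the ATF4 response alone among these lists stayed past the threshold, at adjusted p = 0.0185, and the others ranged from 0.164 to 0.439.

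TAL1 and KDM6A mRNA were not shown to be lower in the libraries labelled as their knockdown. KDM6A had a log2 fold change of 0.19 in the TAL1-labelled comparison, with a 95% interval of 0.02 to 0.37, and TAL1 had -0.12 in the UTX-labelled one. These values argue against an exchange of the shRNA tables only if each shRNA lowers its target mRNA, which neither comparison showed. Activity of the TAL1 shRNA without doxycycline stays open: the lower of the TAL1-control libraries stood 18.9 CPM above the highest of the other controls, but these differed more from each other, with means of 253 and 187. For KDM6A it stays open as well: UTX-control stood at log2 ratios of -0.88 to TAL1-control and -0.34 to J4-control, where 7.99% and 12.4% of 12670 genes were as low and 3.99% in both, and the controls come from different cells. A loss of protein without a loss of mRNA may also underlie the pattern, and no protein values were analysed here.

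Reads on mitochondrial pseudogenes fell in all 3 comparisons. TMM scaling was argued against as the source, since the treated share of raw reads, which uses no scaling factor, was at most 0.482 of the control share. That share is itself a measure of library composition, so it cannot decide whether composition differed for reasons outside the cells. For GSK-J4, where the median log2 fold change was -6.66, the design and not a test sets doxycycline aside, since neither group is described as receiving it. For the shRNA comparisons, with -2.73 in the UTX-labelled one, doxycycline and the induced shRNA cannot be told apart, since no library had doxycycline alone. Whether the reads came from mitochondrial transcripts, whose own fall could not be tested, stays open: with GSK-J4 the rank correlation with shared 36-base sequence was -0.24, between the bounds set, and 3 pseudogenes sharing none had a median of -6.74, which met a bound against this source, but their mean counts of 6.58 to 19.1 were near the floor, and setting them aside was decided after the result was seen. In the UTX-labelled comparison the rank correlation was -0.104 and the median of those sharing none -2.25, while in the TAL1-labelled one they were -0.316 and -0.06, against a median of -0.81 for those sharing any.

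Log2 fold changes in the TAL1-labelled comparison followed GC content, with a rank correlation across genes of 0.207, and transcript length, with -0.115. Removing each library's trend left the median of the ribosomal list at 0.49 (from 0.54), of mitosis at -0.73 (from -0.74), of DNA replication at -0.66 (from -0.63) and of cholesterol synthesis at 0.90 (from 0.88). The camera adjusted p-values after removal were 3.45e-08, 1.11e-09, 3.24e-10 and 1.75e-05. This argues against the trend as the whole source of these shifts. The biological explanation, an effect of the induced shRNA, was not tested apart from doxycycline, and the shifts also lost their calls with an estimated correlation.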

How the results depend on the processing

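The alternatives for genes shared by all 3 treatments, the removal of GC and length trends, and the correlations without mitochondrial pseudogenes or without a TAL1-KD replicate were chosen only after the data were seen. At an adjusted p of 0.01 the TAL1-labelled counts were 2872 higher and 3046 lower. With a log2 fold change of at least 1 they were 700 and 1761, against 298 and 172 in the UTX-labelled comparison and 1770 and 1618 with GSK-J4. Shared genes at 0.01 numbered 1035 lower (631 by chance) and 1018 higher (561) for TAL1 and UTX, and 1494 (1029) and 1499 (989) for TAL1 and GSK-J4. The fold minimum turned the order of the pairs by count, but relative to chance UTX and GSK-J4 still shared the most. The shared genes were then 42 (11.98) and 45 (10.3) for TAL1 and UTX, and 103 (14.0) and 176 (21.7) for UTX and GSK-J4. For TAL1 and GSK-J4 they were 458 (138) and 248 (58.1). In all 3 at 0.01, 723 were lower and 822 higher. Stricter limits pass fewer genes by construction. The DESeq2 Wald test called 2801 genes higher in the UTX-labelled comparison, and the cause was not tested. Leaving out each library, the TAL1-labelled counts ranged from 2431 to 5869 higher and from 3094 to 6083 lower. The lowest values came without TAL1-control replicate 1, and without TAL1-control replicate 2 the higher genes numbered 2657; fewer libraries were fitted and the lone one was assumed to vary like the others. All other leave-one-out counts were within 1.5 times the reported ones. With a replicate block the counts were 4631 and 5130, 4165 and 4179, and 6829 and 6659. Replicate numbers are not stated to pair libraries, and deviations under the same number correlated across genes at 0.188, -0.0495 and -0.0231. Removal of GC and length trends gave 4714 and 4702 for TAL1 and left the other counts within 1.5 times too, but 1 gene called in the UTX-labelled comparison and 38 called higher and 25 called lower with GSK-J4 had been called the other way. The correlations between comparisons moved by less than 0.1. Camera called 42 list shifts, against 33 with log2 fold changes as the statistic, 31 at a preset correlation of 0.05 and 39 against a background of mean count at least 100. With log2 fold changes the calls ended for apoptosis (adjusted p = 0.0643) and GIMAP genes (0.0836) in the TAL1-labelled comparison, for interferon (0.259), respiratory chain (0.298), ribosomal (0.350) and T-cell receptor genes (0.546) in the UTX-labelled one, and for interferon (0.0575), cholesterol (0.129), ribosomal (0.203), respiratory chain (0.241), T-cell receptor (0.328) and NRF2 genes (0.891) with GSK-J4, while replication histones in the TAL1-labelled (0.0192), myeloid markers in the UTX-labelled (0.00987) and fibroblast markers in the GSK-J4 comparison (0.0341) passed. The preset correlation of 0.05 ended the calls of p53 targets (0.0519), apoptosis and GIMAP genes (both 0.0662) and iron handling (0.0834) in the TAL1-labelled comparison, of T-cell receptor (0.0513), respiratory chain (0.0712) and interferon genes (0.180) in the UTX-labelled one, and of interferon (0.0590), NRF2 (0.0713), apoptosis (0.0784) and T-cell receptor genes (0.137) with GSK-J4. The other background ended those of GIMAP genes (0.0503) and iron handling (0.0925) in the TAL1-labelled comparison and of T-cell receptor genes with GSK-J4 (0.0735). Centring was run on the recomputed and not the deposited fold changes, since counts were given. The medians removed, over genes with a mean count of at least 100, were 0.0359 for TAL1, -0.00374 for UTX and 0.00348 for GSK-J4. The smallest change called was 0.20 on the log2 scale in the TAL1-labelled comparison, against 0.07 in each of the others.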

Other observations

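The list tests in this part were fixed before the data were examined, and the naming of IGLL1 was chosen only after its values were seen.

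Clustered HOX genes, which set positional identity, moved both ways. In the UTX-labelled comparison 7 of 23 measured rose and 3 fell, with HOXB9 at 3.92 (SE 0.46) and HOXA13 at -1.23 (SE 0.21). With GSK-J4, 11 of 26 rose and 8 fell, with HOXB9 at 3.26 (SE 0.15), HOXA6 at -1.18 and HOXA5 at -1.04. In the TAL1-labelled comparison 4 of 24 rose and 7 fell. Camera gave the HOX list adjusted p-values of 0.683, 0.523 and 0.819 in the TAL1-labelled, UTX-labelled and GSK-J4 comparisons. Of 12 NOTCH receptors and targets, 1, 2 and 4 rose and 3, 4 and 5 fell in the same order, with camera adjusted p-values of 0.492, 0.637 and 0.509. SHQ1 fell in each comparison (-0.47, -0.62 and -1.32) while MYC changed by 0.30, -0.21 and -3.44. Of 11 Polycomb repressive complex genes, 3, 3 and 2 rose and 5, 7 and 8 fell, with EZH2, the catalytic subunit, at -0.81 (SE 0.08) in the TAL1-labelled comparison and -0.32 (SE 0.03) in the UTX-labelled one, and PHF1, one that rose, at 1.53 (SE 0.03) with GSK-J4, where the median of the list was -0.22. Camera gave that list adjusted p-values of 0.580, 0.0990 and 0.276.

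Of 5 cyclin-dependent kinase inhibitor genes, 1, 3 and 4 rose and 1 fell in each of the TAL1-labelled, UTX-labelled and GSK-J4 comparisons, with camera adjusted p-values of 0.869, 0.637 and 0.0633. CDKN2C changed by -1.63 (SE 0.09) in the TAL1-labelled comparison and -0.37 (SE 0.03) in the UTX-labelled one, and CDKN1C by 1.04 (SE 0.07) with GSK-J4. Interferon-stimulated genes in the TAL1-labelled comparison included IFIT3 at 2.25 (SE 0.13) and IFIT2 at 1.32 (SE 0.12), with 12 of 24 higher and 6 lower and a camera adjusted p of 0.0884. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, were higher for 5 of 12 in the TAL1-labelled comparison, with HIST1H1D at 1.43, and lower for 5 of 12 in the UTX-labelled one, with HIST1H2AG at -1.10. Camera adjusted p-values for the histones were 0.119 and 0.345.

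Markers of other cell types were few among the measured genes. With GSK-J4, 7 of 9 B-cell markers were higher and 1 lower, and 5 of 6 fibroblast markers were higher and 1 lower, with camera adjusted p-values of 0.22 and 0.0659. IGLL1, a surrogate light chain gene of B-cell precursors, was the B-cell marker that fell, with a log2 fold change of -3.10 (SE 0.06), and it also fell in the TAL1-labelled (-0.46, SE 0.10) and UTX-labelled (-1.01, SE 0.06) comparisons.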
